A study of Mus musculus with 12 samples.

How the data were processed

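RNA-seq was made from bead-purified CD8 T cells of spleen and lymph nodes of female C57BL/6 mice, WT or lacking Cpeb4, at rest or after 48 h of activation. The values are raw read counts per Ensembl gene, deposited as 1 table with a column for each of the 12 libraries. Per the submitters' processing notes the deposited counts came from STAR 2.7.0a and featureCounts (version not given) on the mm10 build. The annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical copies are therefore treated as uncertain. Per the labels the libraries were made after poly(A) isolation and amplified with 9 PCR cycles. The labels also mention removal of rRNA from input samples, without saying whether these libraries are such samples. Libraries were grouped by the genotype and state in their labels, and 1 WT library of 48 h (number 3039) without a time point tag was placed by its title. No column was left unused.

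The table held 55573 genes, of which 55480 matched the GENCODE M21 annotation by Ensembl identifier and 93 did not. Symbols, positions and biotypes came from that annotation. Between 26.4% and 29.0% of each library's counts fell on pseudogenes. As one example, Pgk1 averaged 1719 CPM (counts scaled to a common total per library) and its processed pseudogenes Pgk1-rs7 and Gm5537 1327 and 1328 CPM, so that values of such genes and of their copies are uncertain. Other pairs were Tpi1 with Tpi-rs11 (666.5 and 93.98 CPM), Hsp90ab1 with Gm12346 (2245 and 539.1 CPM) and Ak4 with Ak3l2-ps (49.13 and 7.439 CPM). Gapdh was counted at 154.6 CPM.

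Counts were scaled by the TMM method (factors 0.9585 to 1.065) and filtered with filterByExpr by group, which left 20073 genes. Differences were tested with edgeR's quasi-likelihood F test (robust fit, 1 mean per group over all 12 libraries, common biological coefficient of variation 8.27%). Adjusted p-values are by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The 5 contrasts were activation in WT, activation in KO, genotype at rest, genotype at 48 h and their interaction.

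Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 26 lists of a contrast. Members were also counted when adjusted over the list alone. The lists were CD8 T cell identity, naive and quiescence genes, activation markers and transcription factors, cytotoxic molecules and cytokines, inhibitory receptors, memory-phenotype CD8 genes, DNA replication, mitosis, ER folding with the unfolded protein response, targets of ATF4, glycolysis, the nuclear-encoded respiratory chain and sterol synthesis. The others were ribosome biogenesis, cytosolic ribosomal proteins, amino acid transporters, the type I interferon response, p53 targets, the hypoxia response, regulators of the poly(A) tail and AU-rich elements, and markers of B cells, CD4 and regulatory T cells, NK cells, myeloid and dendritic cells, erythroid cells and platelets, and stromal and endothelial cells. The lists, contrasts, tests, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per contrast, genes with a symbol that were called, had a mean of at least 5 CPM and had every library of one group above every library of the other. From these the 10 with the largest log2 fold change in each direction were named, leaving out antigen receptor and immunoglobulin segments and predicted or clone genes. Up to 4 members with the smallest adjusted p were named per described list, as were Cpeb1 to Cpeb4, and the 5 genes with the smallest p where fewer than 5 passed.

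Summed markers, the mitochondrial share and other composition measures were compared by two-sided exact permutation tests of 3 against 3 libraries, which cannot go below 0.1. There were 68 such tests, of which 39 reached 0.1 (0.174 after Benjamini-Hochberg adjustment). For a gene with no count over the 3 libraries of a group the fold was computed against a floor of 3 counts over the group and is a bound. With 1 to 3 counts the ratio is given with its 95% exact interval. Intervals and floors cover counting error only. The total counts differed by at most a factor of 1.2. The steps were tested on simulated counts for 20073 genes, of which 67, 67 and 66 were changed by 1.5-fold, 2-fold and 4-fold. At 48 h the genotype test recovered 67.2% of 1.5-fold, 91% of 2-fold and 95.5% of 4-fold changes with 10 false calls, and at rest 64.2%, 92.5% and 98.5% with 14. The interaction test recovered 59.7%, 70.1% and 95.5% with 10 false calls. Activation in WT gave 71.6%, 91% and 100% with 10, and activation in KO 76.1%, 92.5% and 100% with 13. In a simulated set with 1 list shifted by 0.5 log2, camera with its preset correlation called 1 list, the shifted one. Genes were simulated independently of each other. In the data the members of a list were correlated (estimated at 0.648 for ribosome biogenesis at 48 h). The simulation therefore does not show how often camera with its preset correlation calls unchanged lists here.

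The alternatives were DESeq2, relative log expression factors in edgeR, no filter beyond 1 count, each contrast's groups fitted alone, limma-voom with the library number as a random block, the number as a fixed block, each library left out in turn, genes of at least 5 CPM for correlations across genes, and windows of 500 kb and 5 Mb around Cpeb4. A fit on protein-coding genes alone was chosen after seeing the data.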

Results

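Messenger RNA of mouse CD8 T lymphocytes was measured by RNA-seq in 12 libraries. The cells came from spleen and lymph nodes of wild-type (WT) animals and of animals lacking Cpeb4 (KO), a protein that binds the 3′ untranslated region of mRNAs and regulates their poly(A) tail and translation. They were purified with CD8-binding beads and either left resting or activated for 48 h. Activation used antibodies to CD3 and CD28 (1 µg/ml each), which engage the T cell receptor complex and a co-stimulatory receptor. It also used the growth factor IL-2 (20 ng/ml). Each of the 4 groups held 3 libraries. The libraries carry numbers, 3039, 3040 and 3041 in WT and 3025, 3027 and 3038 in KO, and each number has 1 resting and 1 activated library. The labels do not say what a number stands for, so p-values here measure the spread between these libraries. They also do not say whether resting cells spent time in culture. They name a poly(A) isolation step, and counts after such a step can depend on the length of the tail as well as on the amount of mRNA. The total count per library ran from 28988768 in KO 3025 at rest to 34799250 in WT 3041 at 48 h. The first principal component of log2 expression held 92.6% of the variance and separated resting from activated libraries.

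Cpeb4 (ENSMUSG00000020300) lies on chromosome 11 from 31872211 to 31935634 on the mm10 build. Its mRNA stood at 33.0, 33.4 and 27.9 CPM (counts scaled to a common library total) in the resting WT libraries 3039, 3040 and 3041, and at 28.2, 25.3 and 27.0 in the resting KO libraries 3025, 3027 and 3038. After 48 h of activation it stood at 18.1, 18.6 and 18.7 CPM in WT and at 10.8, 11.8 and 12.8 in KO. At 48 h every KO library lay below every WT library, with a log2 fold change of −0.65 (SE 0.0855). This left 63.8% of the WT level (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00792). Without the WT library 3041, or the KO libraries 3025 or 3027, the adjusted p became 0.0576, 0.0651 and 0.0523, and the log2 value stayed between −0.71 and −0.59 over all libraries left out. At rest the KO level was 85.3% of the WT level (log2 −0.23, SE 0.0794, adjusted p = 0.64), and 1 KO library lay above the lowest WT library, so that this gene does not check the genotype labels at rest. Which exons the KO allele lacks is not given in the sources used here, and counts per gene cannot separate exons. Cpeb4 fell on activation in both genotypes, by 0.77 on the log2 scale in WT (adjusted p = 1.36e-07) and by 1.19 in KO (adjusted p = 7.13e-10). The difference between these falls was −0.42 (SE 0.117, adjusted p = 0.135). In edgeR it was −0.44 (adjusted p = 0.0293) without the low-count filter and −0.48 (adjusted p = 0.0294) without KO 3038 at 48 h. Of its relatives, Cpeb2 had a log2 difference of 0.40 between KO and WT at 48 h (SE 0.122, adjusted p = 0.0544), which edgeR called without WT 3039 (0.49, adjusted p = 0.0377) and without KO 3038 (0.52, adjusted p = 0.00853). That of Cpeb3 was 0.18 (SE 0.413, adjusted p = 0.858) and has no clear sign, running from −0.12 without KO 3038 to 0.49 without KO 3027. Cpeb1 was too low to be tested.

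**Figure D1:**
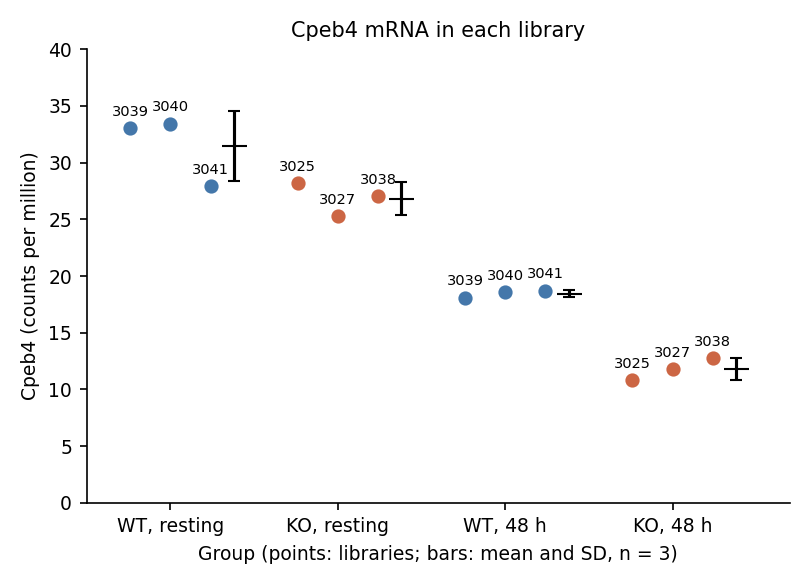
Cpeb4 mRNA in CPM (vertical axis) for each of the 12 libraries, grouped by genotype and state; points are libraries with their numbers, and bars give the mean and SD of 3. At 48 h the KO libraries sit between 10.8 and 12.8, below the WT libraries at 18.1 to 18.7, and at rest the ranges of 25.3 to 28.2 in KO and 27.9 to 33.4 in WT overlap.

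The first comparison asked what 48 h of stimulation did to WT cells. Genes of glycolysis, of the response to low oxygen and of cell division rose together, and markers of other blood and tissue cells fell. All 16 glycolysis genes rose, with a median log2 fold change of 3.48, among them the lactate exporter Slc16a3 (6.65, SE 0.11) and the enzymes Tpi1 (4.96, SE 0.08) and Pgk1 (4.55, SE 0.07). All 14 genes of the hypoxia response rose, with a median of 4.15, including the oxygen sensor Egln3 (7.05), the growth factor Vegfa (6.88) and the mitophagy receptor Bnip3 (6.32). All 21 DNA replication genes rose (median 2.49, Cdc6 4.09, Cdc45 3.80, Rrm1 3.13), as did all 20 mitosis genes (median 4.15, Cdk1 4.28, Aurka 3.86) and all 20 sterol synthesis genes (median 2.55). Among the effector genes, the cytotoxic protease Gzmb went from 9.20 ± 3.17 to 2469 ± 299 CPM (SD, n = 3).

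Some of the genes with the largest increases in WT cells had few counts at rest. Vldlr, a lipoprotein receptor, had 3 counts over the 3 resting libraries and 39.7 ± 1.22 CPM at 48 h, a ratio of 1.33e+03 with a 95% counting interval of 456 to 6.47e+03. Smtnl2 rose with a ratio of 758 (259 to 3.68e+03), Pkp2 with 380 (130 to 1.85e+03) and the Ak4-like pseudogene Ak3l2-ps with 468 (160 to 2.27e+03), each from 3 resting counts. Resting counts above 3, though not always by much, stood behind other log2 increases. These were of the mitochondrial proteins Mgarp (8.85, SE 0.168) and Ak4 (8.59, SE 0.133) and the collagen prolyl hydroxylase P4ha2 (8.64, SE 0.176). The metallothionein Mt2 (8.11, SE 0.204), the glutaminase Gls2 (8.07, SE 0.264) and Gzmb (8.07, SE 0.334) were the others. The activation markers rose in 15 and fell in 5 of 22 genes (median 1.44), led by the IL-2 receptor chain Il2ra (6.38), the co-stimulatory receptor Tnfrsf9 (5.47) and the transcription factor Bhlhe40 (4.66). Of the inhibitory receptors 6 rose and 3 fell among 10. Ctla4 stood at 5.73, Lag3 at 4.09, Tigit at 3.97 and Cd274, a listed gene that codes for a ligand, at −1.24. Targets of the stress-responsive factor ATF4 rose in 18 of 19 genes (median 2.02), among them the serine synthesis enzyme Psat1 (2.98) and the folate enzyme Mthfd2 (2.11). Nuclear genes of the respiratory chain rose in all 15 tested members, by less (median 0.45, Cox5a 1.05, Atp5b 1.02).

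Genes of the naive and quiescent state fell in 18 of 20 members (median −1.13), including the transcription factor Klf3 (−2.92), the antiproliferative gene Btg1 (−1.83) and the IL-7 receptor Il7r (−1.58), while the survival gene Bcl2 rose by 1.36. Type I interferon response genes fell in 17 of 21 (median −2.29, Oasl2 −5.88, Rtp4 −4.17, Irf7 −3.12). Markers of other cells fell without exception among the tested B cell (16), myeloid (19), NK cell (8) and erythroid or platelet genes (8), and in 5 of 7 stromal genes. Their summed expression in WT went from 4978 ± 626 to 226 ± 16.6 CPM for B cells, from 1088 ± 289 to 9.62 ± 0.547 for myeloid and dendritic cells, from 78.3 ± 19.9 to 7.90 ± 1.74 for NK cells and from 152.6 ± 98.8 to 1.47 ± 0.0999 for erythroid cells and platelets (SD, n = 3). With undetected genes set at their bound the median log2 changes of the myeloid, erythroid and stromal lists were −9.46, −7.48 and −4.40, and that of the B cell list was −8.44. Among the largest decreases, C1qa of the myeloid list, with 6032 counts over the resting libraries and no count at 48 h, was at least 1.96e+03-fold lower. Cd5l and Cd300a were at least 1.33e+03-fold and 868-fold lower. The iron exporter Slc40a1 had a ratio of 1.58e+04 (2.84e+03 to 6.25e+05) from 1 count at 48 h. Tgfbi, Treml4, Hpgd, S100a9, Cacna1e and Clec4n had no count at 48 h either and were at least 814-fold, 768-fold, 748-fold, 731-fold, 712-fold and 655-fold lower.

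In all, 15131 of 20073 genes passed in WT, 7264 higher and 7867 lower (edgeR quasi-likelihood test, adjusted p under 0.05), with 3406 at least 2-fold higher and 3758 at least 2-fold lower. Each member counted as risen or fallen above also passed when adjusted over the list alone, with the same counts. By camera with its preset correlation the adjusted p was 3.55e-59 for glycolysis, 1.26e-39 for hypoxia, 4.95e-35 for DNA replication and 5.94e-34 for mitosis. With an estimated correlation these held at adjusted p = 0.000878, 0.000129, 0.00636 and 0.0353. Sterol synthesis (2.75e-22), activation markers (7.25e-10), B cell markers (2.36e-39) and myeloid markers (2.35e-23) also held, at adjusted p = 0.0481, 0.0317, 0.0146 and 0.0373 with an estimated correlation. The other called lists lost their call with an estimated correlation: adjusted p = 0.0914 for the ATF4 targets (preset 4.22e-09), 0.118 for inhibitory receptors (0.00105), 0.278 for naive genes (2.29e-05) and 0.433 for interferon genes (6.35e-05). The same held for the respiratory chain, with adjusted p = 0.536 (0.0118), and for other cells, with 0.38 for NK cell (0.0104), 0.536 for erythroid (0.0247) and 0.0972 for stromal markers (0.0252). Mitochondrially encoded genes took 3.21 ± 0.390% of counts in resting and 1.48 ± 0.0947% in activated WT libraries (SD, n = 3). The labels give 5% oxygen for resting and activated libraries alike. They do not say whether resting cells were cultured, so activation and 48 h of culture are not separated. The resting libraries also held more RNA of other cells than those of 48 h. Falls of other genes, the interferon genes and Cpeb4 included, therefore need not lie in the CD8 T cells. This was not tested.

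**Figure D2:**
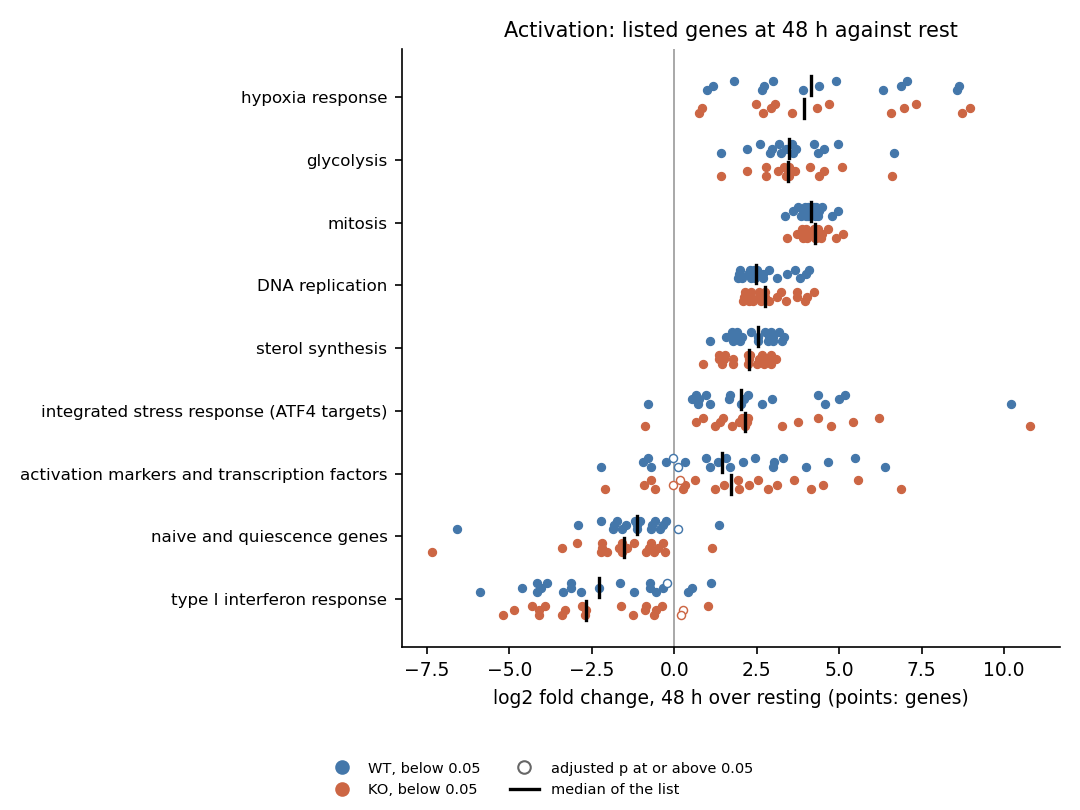
Log2 fold change at 48 h over rest (horizontal axis) of each tested gene of 9 lists, in WT (blue) and KO (orange); filled points passed at an adjusted p under 0.05 and black bars are list medians. Hypoxia, glycolysis and mitosis genes lie to the right in both genotypes, with WT medians of 4.15, 3.48 and 4.15, and naive and interferon genes mostly to the left, with medians of −1.13 and −2.29.

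Other lists moved in both directions in WT cells or were not called as a list. Of the cytotoxic molecules and cytokines 9 rose and 3 fell among 18 tested (camera on the edgeR fit, adjusted p = 0.305), with Gzmc at 4.54, Ifng at 4.04 and Fasl at 2.25 and with the chemokine Xcl1 at −2.91. Amino acid transporters rose in 6 and fell in 1 of 10 (0.121, Slc1a4 3.23, Slc7a5 2.53). ER folding genes rose in 7 and fell in 10 of 23 (0.514, Canx 0.91, Syvn1 −1.65), and ribosome biogenesis genes rose in 6 and fell in 6 of 20 (0.836, Npm1 1.43, Ncl 1.03, Rrp9 −0.78). Cytosolic ribosomal protein genes rose in 3 and fell in 11 of 20 (0.305, Rps2 0.75, Rps24 −0.88). CD8 T cell identity genes rose in 2 and fell in 6 of 12 (0.305, Thy1 0.45, Cd5 −0.85, Cd8a −0.58), and memory-phenotype genes rose in 2 and fell in 8 of 14 (0.314, Klrk1 1.33, Cxcr3 −2.22). For p53 targets the counts were 6 and 4 of 13 (0.227, Cdkn1a 4.59), for regulators of the poly(A) tail and of AU-rich elements 8 and 9 of 20 (0.305, Zfp36 −2.11), and for CD4 and regulatory T cell markers 2 and 3 of 6 (0.305, Cd4 −3.10).

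The second comparison asked the same of KO cells. Their response had the same leading genes: the 10 largest increases were those of WT, with Vldlr at a ratio of 2.08e+03 (575 to 1.72e+04), Smtnl2 at 611 (209 to 2.97e+03) and Gls2 at 426 (146 to 2.07e+03). Their log2 changes were 9.09 for Mgarp, 8.96 for Ak4, 8.72 for P4ha2, 8.16 for Mt2, 7.96 for Gzmb, 7.86 for Ak3l2-ps and 7.77 for Pkp2. Glycolysis (16 of 16, median 3.46), hypoxia (14 of 14, 3.94), DNA replication (21 of 21, 2.75), mitosis (20 of 20, 4.26) and sterol synthesis genes (20 of 20, 2.26) rose. ATF4 target (18 of 19, 2.15), respiratory chain (15 of 15, 0.73) and activation marker genes (16 of 22, 1.72, and 17 when adjusted over the list alone) rose too, while 4 activation markers fell. Naive (19 of 20, −1.51) and interferon genes (18 of 21, −2.67) fell. Ribosome biogenesis genes rose in 11 and fell in 1 of 20 (median 0.44, Npm1 1.54, Ncl 1.26). ER folding genes rose in 12 and fell in 5 of 23 (median 0.20, Hsp90b1 1.29, Canx 1.17), and amino acid transporters rose in 7 of 10 (Slc7a5 2.84). The B cell factor Pax5 was at least 3.07e+03-fold lower, and the macrophage genes Mrc1 and Cd5l at least 1.18e+03-fold and 1.01e+03-fold lower. Pira2, Fcrla, Cacna1e and Treml4 were at least 912-fold, 885-fold, 687-fold and 634-fold lower, all with no count at 48 h. The ratios were 7.45e+03 (2.06e+03 to 6.15e+04) for the lysozyme Lyz2, 6.25e+03 (1.73e+03 to 5.16e+04) for Slc40a1 and 6.11e+03 (1.69e+03 to 5.04e+04) for the B cell gene Ms4a1.

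In KO cells 15502 genes passed, 7444 higher and 8058 lower (edgeR, adjusted p under 0.05). Summed markers fell from 4197 ± 238 to 201.5 ± 9.70 CPM for B cells, from 865 ± 82.2 to 8.05 ± 1.48 for myeloid cells, from 86.2 ± 5.67 to 12.6 ± 3.58 for NK cells and from 37.9 ± 19.6 to 0.710 ± 0.222 for erythroid cells and platelets. List medians with undetected genes at their bound were −8.18 for B cell, −9.05 for myeloid, −5.22 for erythroid and −1.52 for stromal markers. By camera the adjusted p was 4.02e-57 for glycolysis, 9.81e-37 for hypoxia, 1.73e-36 for DNA replication, 5.83e-33 for mitosis, 1.38e-10 for activation markers, 3.98e-37 for B cell and 1.69e-21 for myeloid markers, and these held with an estimated correlation (adjusted p = 0.000992, 0.000607, 0.0121, 0.0448, 0.0206, 0.0121 and 0.0448). Sterol synthesis (6.01e-17, estimated adjusted p = 0.0987), the ATF4 targets (1.14e-10, 0.078), naive genes (1.62e-07, 0.147), interferon genes (4.21e-05, 0.405) and the respiratory chain (0.000627, 0.405) were called with the preset correlation alone. The same was true of inhibitory receptors (0.00165, 0.137), of which 6 rose and 3 fell among 10, and of the NK cell (0.00882, 0.337), stromal (0.0309, 0.106) and amino acid transporter lists (0.0311, 0.422). Not called were erythroid markers (0.0597), ribosome biogenesis (0.101), CD8 identity (0.101, 1 rose and 9 fell of 12), cytotoxic genes (0.159, 11 and 3 of 18), memory-phenotype genes (0.159, 2 and 10 of 14), poly(A) regulators (0.159, 8 and 10 of 20), p53 targets (0.246, 5 and 3 of 13), CD4 markers (0.265, 1 and 3 of 6), ribosomal proteins (0.272, 2 and 13 of 20) and ER folding (0.307). Across the 20073 genes, which are not independent replicates, the log2 changes of the 2 genotypes had a Pearson r of 0.975 and a slope of 0.972, and 92.3% shared their sign. Both responses called 6645 genes higher (2694 for independent lists) and 7144 lower (3158), and 27 in opposite directions.

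The third comparison set resting KO against resting WT cells. Genes of red blood cells and platelets stood lower in KO and several receptors of the natural killer gene complex higher, but no gene passed the adjusted test. The lowest p-values belonged to the red cell anion exchanger Slc4a1 (log2 −2.46, SE 0.369, adjusted p = 0.0824), the Ly49 receptor genes Klra9 (1.06, SE 0.172, 0.0824) and Klra6 (0.94, SE 0.161, 0.0917), the chemokine Cxcl13 (−3.05, SE 0.446, 0.0824) and the antibody segment Ighv1-82 (−0.93, SE 0.145, 0.0917). In the erythroid and platelet list 0 of 8 passed over all genes and 7 of 8 were lower when adjusted over the list alone, with a median of −2.06. Beside Slc4a1 these included the globin gene Hbb-bt (−2.02, SE 0.571), the platelet chemokine Ppbp (−2.13, SE 0.54) and the heme enzyme Alas2 (−1.52, SE 0.462). Their summed level was 245, 48.4 and 164 CPM in WT 3039, 3040 and 3041 and 18.7, 37.1 and 57.9 CPM in KO 3025, 3027 and 3038 (two-sided exact permutation p = 0.2, where 3 against 3 cannot go below 0.1). NK cell markers had a median of 0.60, with 3 of 8 higher when adjusted over the list alone (Klra7 0.91, SE 0.275, Klre1 0.75, SE 0.192). Their summed level was 86.2 ± 5.67 CPM in KO and 78.3 ± 19.9 in WT (SD, n = 3, two-sided exact permutation p = 0.5), and highest in WT 3039 (101.3). Memory-phenotype CD8 genes had a median of 0.20, with 2 of 14 higher when adjusted over the list alone (Klrc2 0.85, SE 0.177). Reads of such Klra and Klrc genes can be shared between near-identical family members, so their single values are uncertain.

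The count of 0 of 20073 genes came from edgeR, with 1345 genes at an unadjusted p under 0.05 where 1004 would be found by chance. DESeq2 called 20, limma-voom 5 and edgeR without the low-count filter 310. By camera with the preset correlation 15 lists passed, none of them with an estimated correlation and none by fry. The smallest were those of erythroid and platelet markers (adjusted p = 1.36e-15, estimated 0.152), B cell markers (median −0.25, 3.24e-08, 0.309), memory-phenotype genes (2.91e-07, 0.162), ER folding (−0.12, 9.78e-07, 0.309) and myeloid markers (−0.33, 5.54e-06, 0.357). Next came sterol synthesis (0.13, 3.32e-05, 0.465), NK cell markers (0.000118, 0.309), the respiratory chain (−0.09, 0.000382, 0.465) and cytotoxic genes (0.10, 0.00127, 0.357). The others were ribosomal proteins (−0.06, 0.00127, 0.596), interferon genes (−0.15, 0.00241, 0.577), naive genes (0.07, 0.00251, 0.501), mitosis (−0.14, 0.0144, 0.644), poly(A) regulators (0.06, 0.024, 0.357) and DNA replication (−0.07, 0.0271, 0.596). Without WT 3040 at rest the mitosis median was 0.0794 (adjusted p = 0.00687), of the other sign, and that of DNA replication −0.0138 (0.791). The other 11 were not called: activation markers (0.0516), stromal (0.0878), inhibitory receptors (0.119), CD8 identity (0.127), ribosome biogenesis (0.275), p53 targets (0.288), amino acid transporters (0.381), hypoxia (0.504), CD4 markers (0.593), ATF4 targets (0.714) and glycolysis (0.722). The library WT 3039 held the highest resting level of 5 of the 6 lists of other cell types. Without it the B cell median was −0.07 (adjusted p = 0.0821), the myeloid median −0.06 (0.0296), the erythroid median −1.52 and the NK cell median 0.77. Total counts at rest were lower in every KO library than in every WT library.

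**Figure D3:**
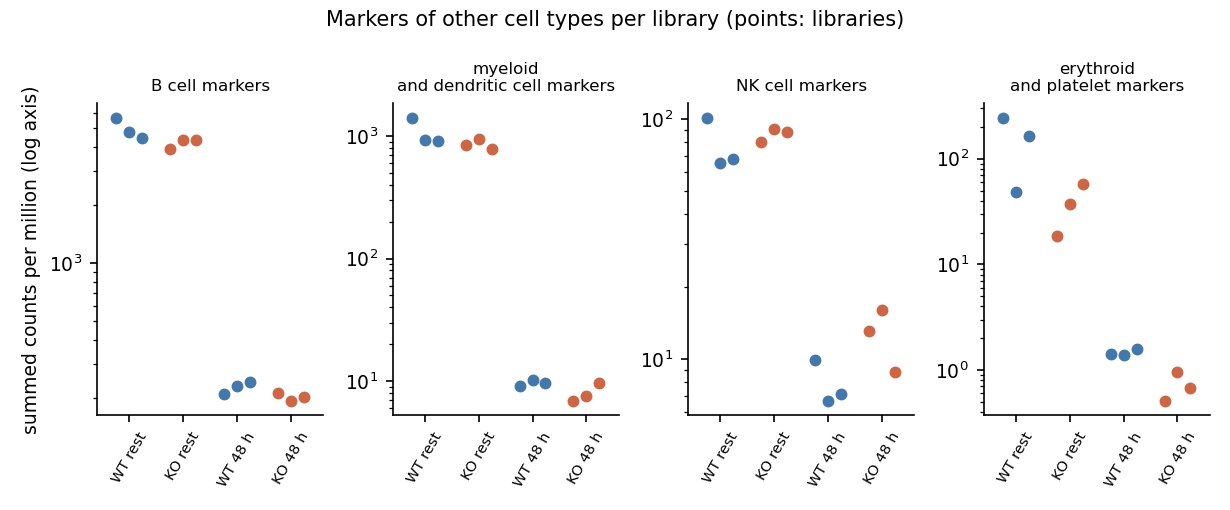
Summed CPM (log axis) of markers of B cells, myeloid and dendritic cells, NK cells, and erythroid cells and platelets, for each library (points) of the WT (blue) and KO (orange) groups at rest and at 48 h. B cell markers fell from between 3922 and 5674 at rest to between 192 and 241 at 48 h, and erythroid and platelet markers at rest ran from 18.7 to 57.9 in KO and from 48.4 to 245 in WT.

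The fourth comparison, and the one closest to the aim of the series, set KO against WT cells after 48 h of activation. Genes of ribosome biogenesis, ER folding, the ATF4 response and amino acid transport were among those called higher in KO, while as lists these passed by camera with its preset correlation and not with an estimated one (adjusted p = 0.228, 0.228, 0.23 and 0.228). Ribosome biogenesis genes were higher in 16 of 20 (median log2 0.42), among them the nucleolar proteins Nolc1 (0.63, SE 0.107), Dkc1 (0.46, SE 0.0871), Rrp9 (0.43, SE 0.0798) and Gar1 (0.40, SE 0.0706). ER folding genes were higher in 11 of 23 (median 0.22), with the chaperones Hyou1 (0.51, SE 0.0826) and Hspa5 (0.49, SE 0.0863) and the folding factors Manf (0.38) and Dnajb11 (0.33). ATF4 targets were higher in 8 of 19 (median 0.32, Nupr1 0.88, Shmt2 0.41, Atf4 itself 0.32, Psat1 0.32) and amino acid transporters in 4 of 10 (median 0.21, Slc7a5 0.55, Slc7a1 0.44, Slc1a4 0.40, Slc3a2 0.31).

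The 5 lists that follow did not hold with an estimated correlation either, with an adjusted camera p of 0.228 for activation markers and for cytotoxic genes, 0.368 for naive genes, 0.566 for sterol synthesis and 0.573 for interferon genes. Activation markers were higher in KO in 5 of 22 (median 0.19), with the transferrin receptor Tfrc at 0.54, Il2ra at 0.46, Batf at 0.42 and Myc at 0.33. Among cytotoxic molecules and cytokines 4 of 18 were higher (median 0.37): the chemokine Ccl3 (0.92), the cytokines Lta (0.78) and Tnf (0.71) and the granzyme inhibitor Serpinb9 (0.39). Naive and quiescence genes were lower in 4 of 20 (median −0.25, Ccr7 −0.42, Pdcd4 −0.38, Txnip −0.37, Btg1 −0.36), sterol synthesis genes in 4 of 20 (median −0.17, Fdft1 −0.39, Fdps −0.35, Mvd −0.34, Dhcr7 −0.30) and interferon genes in 2 of 21 (median −0.23, Stat2 −0.34). The gene with the lowest p was the ER glucosidase Mogs, on chromosome 6 from 83115496 to 83118898 (0.86, SE 0.0825, adjusted p = 0.000173). The largest increases were of the TNF receptor family member Tnfrsf8 (1.16, SE 0.233, adjusted p = 0.0174), the chemokine receptor Ccr4 (1.05, SE 0.218, 0.0182), Fgl2 (0.97), Bend3 (0.86), Mogs, Ryk (0.85), Nefh (0.82), the kinase Sgk1 (0.80), Lta (0.78) and Neto2 (0.75). The largest decreases were of the T cell surface gene Cd7 (−1.13, SE 0.279, 0.0439), Dapl1 (−1.06, SE 0.267, 0.0477), the potassium channel Kcnc1 (−1.02), Nmnat2 (−1.01), Nsg2 (−0.92), Sh3pxd2a (−0.85), Grin1 (−0.85), Dnm1 (−0.84), H2-Oa (−0.81) and Mfsd13a (−0.80). Dnm1 overlaps the more abundant Ciz1 on the opposite strand, and Grin1 and H2-Oa overlap less abundant genes, so their values are uncertain. The same holds for some list members named for 48 h. Fdft1 (46.2 CPM) overlaps Ctsb (229 CPM), and Manf (53 CPM) overlaps Dcaf1 (60.9 CPM) and Rbm15b (51.1 CPM). Rrp9, Dkc1 and others overlap less abundant genes. Also higher in KO were the memory-phenotype genes Eomes (0.30) and Id2 (0.32), while Klrd1 was lower (−0.36) beside Dapl1.

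At 48 h 1375 genes passed (6.85% of those tested), 850 higher and 525 lower in KO (edgeR, adjusted p under 0.05), with a median size of 0.37 log2 and only 31 and 25 of them at 2-fold or more. Protein-coding genes made up 1156 of the calls, 687 higher and 469 lower. Pseudogenes, which can share reads with their parent genes, made up 165, of which 143 were higher and 22 lower. The libraries of the groups did not overlap for 5058 genes (25.2%, against 10% by chance), and 1280 of the called genes were among them. The count depended on single libraries: it was 4 without WT 3040, 1 without WT 3041, 1 without KO 3025 and 2 without KO 3027, but 1642 without WT 3039 and 2776 without KO 3038. At an adjusted p under 0.1 the first 4 of these fits called 769, 544, 176 and 521. All 1375 genes had the same sign and an unadjusted p under 0.05 in each of the 6 fits, but they were chosen on the same libraries, so this is no independent check. The largest adjusted p of Mogs under any alternative was 0.00647. The count was 2 at an adjusted p under 0.01 (Mogs and Cpeb4), 416 under 0.02 and 2493 under 0.1. It was 547 when the 48 h groups were fitted alone and 2169 without the low-count filter.

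Adjusted over the list alone, 19 of 20 ribosome biogenesis, 14 of 23 ER folding, 11 of 19 ATF4 target, 7 of 10 amino acid transporter, 7 of 22 activation marker and 7 of 18 cytotoxic genes were higher in KO (1 cytotoxic gene was lower), and 4 naive, 8 sterol synthesis and 3 interferon genes were lower. By camera the adjusted p was 4.26e-22, 1.55e-09, 2.03e-06, 2.2e-05, 0.00012 and 4e-06 for the first 6 and 4e-06, 1.83e-05 and 0.00443 for the last 3. With an estimated correlation none held: adjusted p = 0.228, 0.228, 0.23, 0.228, 0.228 and 0.228, and 0.368, 0.566 and 0.573. Fry, which asks whether the genes of a list move one way and not whether they do so more than others, gave 0.0206, 0.0206, 0.0292, 0.0206, 0.0206 and 0.0292 for the first 6 and 0.105, 0.14 and 0.337 for the last 3. With any single library left out the median stayed between 0.37 and 0.50 for ribosome biogenesis and between 0.18 and 0.28 for ER folding. Beside these lists, CD8 T cell identity genes summed to 3349 ± 81.3 CPM in KO and 3565 ± 83.8 in WT, and mitochondrially encoded genes took 1.66 ± 0.113% of counts in KO and 1.48 ± 0.0947% in WT (SD, n = 3, two-sided exact permutation p = 0.1 for each, the smallest possible, and 0.174 adjusted over 68 such tests).

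**Figure D4:**
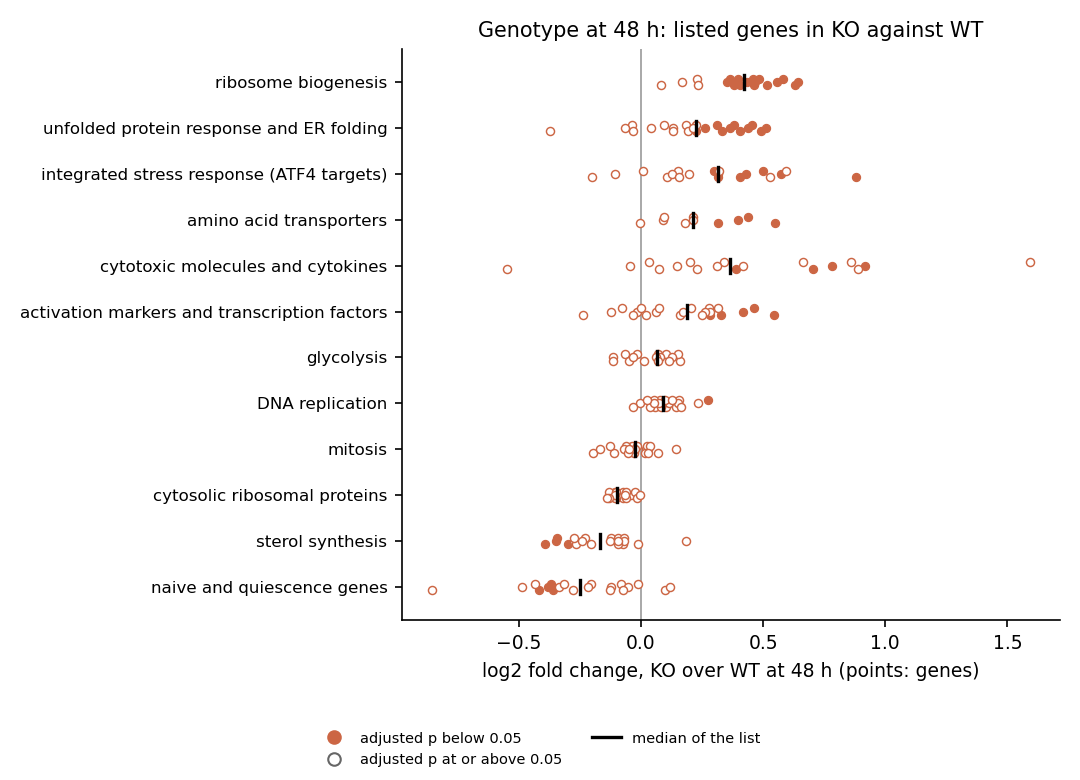
Log2 fold change of KO over WT at 48 h (horizontal axis) for each tested gene of 12 lists; filled points passed at an adjusted p under 0.05 and black bars are list medians. Ribosome biogenesis genes lie to the right of 0 with a median of 0.42, and sterol synthesis and naive genes mostly to the left with medians of −0.17 and −0.25.

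Of the remaining lists at 48 h, CD8 identity (median −0.14, camera adjusted p = 0.00482, estimated 0.566, Cd3e lower at −0.24), the respiratory chain (0.10, 0.00475, 0.566, Cycs higher at 0.47) and B cell markers (−0.44, 0.00482, 0.566, none passed) were called with the preset correlation. So were DNA replication (0.09, 0.00953, 0.566, Tyms higher at 0.28) and ribosomal proteins (−0.10, 0.0233, 0.732, none passed). Not called were NK cell markers (0.0557, Klrb1c higher at 1.89), erythroid markers (0.119, Itga2b lower at −1.16), p53 targets (0.23, Sesn1 and Trp53inp1 lower at −0.42 and −0.33), hypoxia (0.325, Ndrg1 and Pdk1 lower at −0.33 and −0.31) and stromal markers (0.364, Pecam1 lower at −0.34). Nor were glycolysis (0.433, none passed), inhibitory receptors (0.508, none passed), memory-phenotype genes (0.534), poly(A) regulators (0.6, Tob2 and Elavl1 higher at 0.39 and 0.26), CD4 markers (0.6, none passed), mitosis (0.605, none passed) and myeloid markers (0.968, Xcr1 higher at 1.76).

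**Figure D5:**
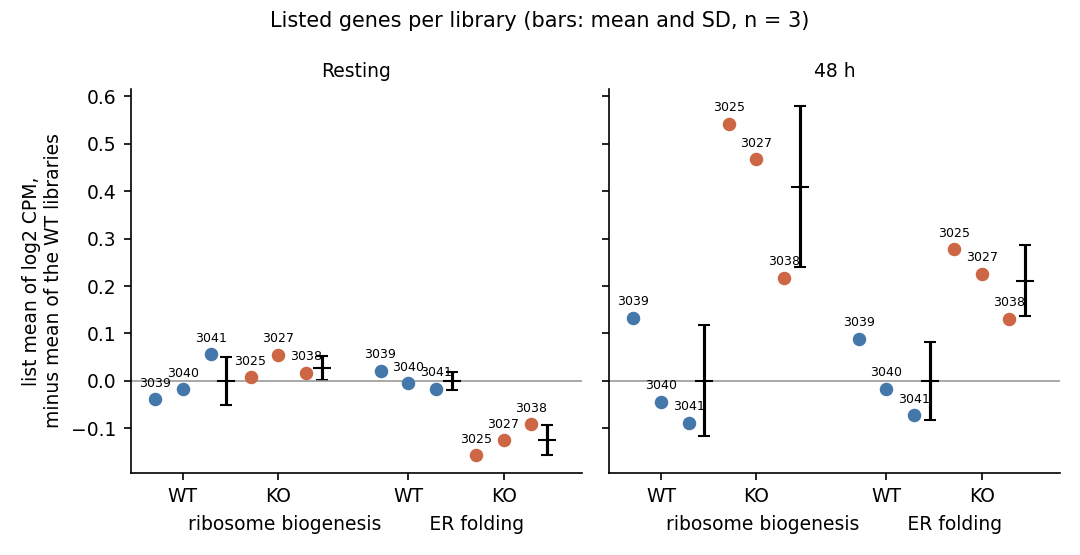
Mean log2 CPM of the ribosome biogenesis and ER folding lists in each library, minus the mean of the WT libraries of the same state (vertical axis); points are libraries with their numbers, and bars give the mean and SD of 3. At 48 h the ribosome biogenesis values are 0.54, 0.47 and 0.22 in KO 3025, 3027 and 3038 and run from −0.09 to 0.13 in WT. At rest they run from −0.04 to 0.06 over both genotypes. The ER folding values at 48 h run from 0.131 to 0.277 in KO and from −0.0727 to 0.0893 in WT. At rest they lie the other way, from −0.157 to −0.0917 in KO and from −0.0167 to 0.0213 in WT.

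The fifth comparison tested whether activation changed genes by different amounts in the 2 genotypes, the only direct test of that difference. ER folding and ribosome biogenesis genes had the lowest p-values among the lists, with positive medians, but neither held with an estimated correlation (adjusted p = 0.177 and 0.432) and no single gene passed over all genes. ER folding genes had a median difference of 0.38 with 15 of 23 passing when adjusted over the list alone (Hspa5 0.68, SE 0.122). Their median in KO against WT was 0.22 at 48 h and −0.12 at rest (1 of 23 positive), so both states contributed. Ribosome biogenesis genes had a median of 0.43 with 16 of 20. The lowest p-values were those of Mogs (0.67, SE 0.116), the Hsp90 co-chaperone Fkbp4 (0.68, SE 0.122), Hspa5, the phosphatase Ppm1j (−0.68, SE 0.127) and Gm12346 (0.70, SE 0.135), a processed pseudogene that can share reads with Hsp90ab1, all at an adjusted p of 0.122. Ppm1j overlaps another gene, so its value is uncertain.

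The count of 0 came from edgeR, with 3157 genes at an unadjusted p under 0.05 (1004 by chance). DESeq2 called 386, limma-voom 0 and edgeR without the low-count filter 809, and without KO 3038 at 48 h edgeR called 1150, without WT 3039 at 48 h 19. By camera 10 lists passed with the preset correlation and 0 with an estimated one. ER folding (adjusted p = 1.12e-16, estimated 0.177), ribosome biogenesis (4e-15, 0.432), sterol synthesis (median −0.27, 2.72e-09, 0.45), naive genes (−0.32, 6.1e-09, 0.432) and the respiratory chain (0.18, 3.03e-06, 0.45) had the lowest p. They were followed by ATF4 targets (0.30, 0.000185, 0.45), DNA replication (0.16, 0.000393, 0.45), CD8 identity (−0.16, 0.00126, 0.45), amino acid transporters (0.26, 0.00305, 0.45) and activation markers (0.14, 0.0458, 0.45). Fry called ER folding alone (adjusted p = 0.0266). The remaining 16 lists had adjusted camera p-values from 0.0608 for cytotoxic genes to 0.943 for NK cell markers.

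The genotype difference at rest and that at 48 h had a Pearson r of 0.134 over 20073 genes, with 50.6% sharing a sign. The r was 0.269 for genes of at least 5 CPM and 0.00778 without the low-count filter. Near Cpeb4, 37 tested genes lay within 2 Mb, and 1 of them differed between genotypes at 48 h, Nsg2 on chromosome 11 from 32000463 to 32059202 (log2 −0.92, SE 0.232, adjusted p = 0.0476). That share was not above the 6.85% of genes called elsewhere (two-sided Fisher's exact test, p = 0.515), and at rest and in the interaction none of the 37 passed. A share over 37 genes does not test an effect of the allele on a single neighbour. Nsg2 was the next tested gene downstream of Cpeb4, and such an effect on it was not tested.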

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

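Of the tests in this part, the other splits of the libraries and the trend with GC content and length were planned, and all the others were chosen after the result was seen.

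The median difference between the activation responses of KO and WT cells was positive for ER folding and ribosome biogenesis genes and negative for sterol synthesis genes, and no list held with an estimated correlation. The 10 lists given here stand out because the test of the difference between the genotypes' responses passed by camera with its preset correlation. The adjusted p was 1.12e-16 for ER folding, 4e-15 for ribosome biogenesis, 2.72e-09 for sterol synthesis, 6.1e-09 for naive genes and 3.03e-06 for the respiratory chain. It was 0.000185 for ATF4 targets, 0.000393 for DNA replication, 0.00126 for CD8 identity, 0.00305 for amino acid transporters and 0.0458 for activation markers. With an estimated correlation the adjusted p of ER folding was 0.177, of ribosome biogenesis 0.432 and of naive genes 0.432, and that of the other 7 was 0.45, so none of the 10 held.

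The first pattern is the higher level of ribosome biogenesis and ER folding genes in KO at 48 h. A trend with GC content and exon length is argued against. The median difference of the 43 listed genes was 0.37 after that trend was taken out and 0.36 before. The bootstrap SD of the value after was 0.054, from resampling genes and not libraries. The trend itself was small, with an SD of 0.019 log2 over all genes. Open is whether KO 3025 and 3027 differ for a reason other than the allele. KO 3038 was placed between the WT mean at 0 and the mean of KO 3025 and 3027 at 1. Its median place was 0.417 over the 38 of 43 genes more than 0.1 log2 higher in KO 3025 and 3027. That lies neither at the WT mean nor with the other KO libraries. The bootstrap SD of 0.017 came from resampling genes and leaves out the spread between libraries. The choice of the 38 genes can lower the place of KO 3038, and by the mean difference over all 43 genes it was 0.465. KO 3038 lay above all WT libraries for 30 of 43 genes and above the WT mean for 20 of 20 ribosome biogenesis genes. In the mean of that list it stood at 0.218, WT 3039 at 0.133 and KO 3027 at 0.467. Over all genes KO 3038 lay nearer to WT. On the first principal component of the 48 h libraries (42.1% of variance) it stood at −4.83. WT ran from −27.7 to −7.75 there, and KO 3025 and 3027 stood at 35.4 and 27.2. On that of the resting libraries (28.3%) KO 3038 stood at −5.71, WT from −20.6 to −8.26 and KO 3025 and 3027 at 32.4 and 16.9. KO cells might also lie further along the course of activation, which stays open. The pattern's own lists were not called for activation in WT. Ribosome biogenesis had a median of 0.0732 there and ER folding of −0.106 (camera adjusted p = 0.836 and 0.514). A longer way along the change from rest to 48 h would not by itself raise both lists. States between or after these times were not sampled. Of 6 lists raised by activation in WT, 3 were positive in KO against WT at 48 h. Activation markers, ATF4 targets and inhibitory receptors, raised as well but not among the 6, had positive medians (0.19, 0.32 and 0.10). No list was lower with an estimated correlation, but that test called none of the 26 lists at 48 h and so could not decide. Of the 850 genes higher in KO, activation in WT raised 459 and lowered 231. Of the 525 lower in KO it lowered 269 and raised 159. These counts share the WT libraries of 48 h. The genotype itself remains an open explanation.

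The second pattern is that Cpeb4 reads remain in the KO libraries. Reads of Cpeb2 and Cpeb3 counted both there and at Cpeb4 are argued against as the whole source, first by a test at rest alone and then in both states. The mean ratio of Cpeb4 to the sum of Cpeb2 and Cpeb3 in KO was 2.25 at rest (SD 0.0848, lowest 2.17). At 48 h it was 1.51 (SD 0.321, lowest 1.28). Reads of these genes counted at Cpeb4 alone would be missing from that sum, so the ratio does not test them. A swap between a KO and a WT library of 48 h is argued against, since 0 of 3 KO libraries reached the lowest WT library. For a swap at rest the test was first written over both states, met by 1 of 6 libraries, and then divided by state with an allowance for counting error: 1 of 3 resting KO libraries lay above the lowest WT library, by less than counting error, which leaves this open. An allele that lacks part of the gene and still makes mRNA could leave such reads, and gene counts do not test it.

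The third pattern is the lower level of erythroid and platelet genes in KO at rest. WT 3039 alone is argued against as the source, since the median difference without it was −1.52. A lower share of CD8 T cells in the WT libraries as a group was first tested by the number of other cell types higher in every WT library (1 of 4), which settled nothing, and that test was replaced. In the new test the erythroid difference between KO and WT stood apart from that of each of the 4 other cell types. The gap was −1.32 log2 at the least (SD between libraries 0.658). The bound was set after the result, all 4 gaps use the same erythroid values, and each group had 3 libraries. The summed erythroid level also overlapped between genotypes (57.9 CPM in KO 3038, 48.4 in WT 3040). A lower share of CD8 T cells as the whole source therefore stays open. A difference in blood left in the tissue or in the animals was not tested and stays open.

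The 10 ways of dividing 6 libraries into groups of 3 are too few for a share under 0.05. The real division gave 15131 calls for activation in WT and 15502 in KO, and the highest of the others 0 in each, so that 1 of 10 divisions gave as many. For genotype at 48 h the real division gave 1375 and the highest other 8 (1 of 10), for genotype at rest 0 and 1 (10 of 10), and for the interaction 0 and 0 (10 of 10).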

How the results depend on the processing

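The counts of genes changed by activation in WT and genes changed by activation in KO stayed within 1.5 times under each alternative. With 1 library left out the counts ran from 14620 to 14808 in WT and from 15010 to 15394 in KO. The test on protein-coding genes alone was chosen after seeing the data and called 1498 genes changed by genotype at 48 h, 806 higher and 692 lower. Relative log expression factors changed no count by over 1.5 times.

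For genotype at 48 h, leaving out 1 library gave from 1 to 2776 genes, the groups fitted alone 547, and no low-count filter 2169, of which 1107 were higher and 1062 lower. At an adjusted p under 0.1 leaving out 1 library gave from 176 to 3969. In each such fit the 1375 genes, chosen on the same libraries, kept their sign and an unadjusted p under 0.05. For genotype at rest DESeq2 called 20 genes, no low-count filter 310 and limma-voom 5, and leaving out 1 library gave 0 to 4. For the interaction DESeq2 called 386, no low-count filter 809, and leaving out 1 library 0 to 1150. The cause was not tested.

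With the library number as a fixed replicate block the interaction had 2 genes against 0 without it, and the counts of genes changed by activation in WT and genes changed by activation in KO were 15114 and 15461. The deviations of libraries with the same number correlated at 0.0619, 0.0722 and 0.0534 in WT 3039, 3040 and 3041 and at 0.0181, 0.108 and 0.165 in KO 3025, 3027 and 3038. Of the 6 numbers all but 3025 correlated best with their own, a hint from the data and not from the design. Against that, the consensus correlation within a number over all genes in limma-voom was −0.0201.

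The log2 difference of Cpeb4 with 1 library left out ran from −0.71 to −0.59 for genotype at 48 h, −0.31 to −0.19 at rest, −0.85 to −0.72 for activation in WT, −1.24 to −1.13 in KO and −0.48 to −0.34 for the interaction. Without KO 3038 at 48 h the interaction had an adjusted p of 0.0294, and without the low-count filter it was −0.44 with an adjusted p of 0.0293 (edgeR), against 0.135. The cause was not tested.

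The r of the activation responses of the genotypes was 0.80 without the low-count filter, 0.986 for genes of at least 5 CPM and 0.967 to 0.972 with 1 library left out. The r of the genotype effects at rest and at 48 h was 0.00778, 0.269 and 0.101 to 0.136. Within 5 Mb of Cpeb4 2 genes were called at 48 h.

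With an estimated correlation camera called 8 lists for activation in WT, 7 in KO, and 0 for genotype at rest, genotype at 48 h and the interaction. Fry called 26 lists for activation in KO, 0 for genotype at rest, 6 at 48 h and 1 for the interaction. Leaving out 1 library gave 16 lists in WT, 16 to 17 in KO, 13 to 16 at rest, 13 to 15 at 48 h and 9 to 13 for the interaction. Without WT 3040 at rest the direction given by camera turned for 3 lists. These were DNA replication at rest (median −0.0138, adjusted p = 0.791), mitosis at rest (0.0794, 0.00687) and mitosis in the interaction (−0.13, 0.0338). The median of DNA replication kept its sign, and that list lost its call. Over all libraries left out these medians ran from −0.11 to −0.0138, from −0.269 to 0.0794 and from −0.13 to 0.233. The cause was not tested. Of 2154 tests of named genes with 1 library left out, 1852 kept their direction and side of the threshold, 278 lost and 24 gained a call. Of the losses 274 were at 48 h between genotypes, where 169 of 450 tests stayed the same, 7 gained a call and 0 changed sign, in genes chosen on the same libraries.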

Other observations

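The 5 lists in this part were chosen after the data were examined, from genes seen among the calls, so that their tests are not independent of the choice. They were first run in part and then completed to whole families, and the adjusted p-values are over these 5 lists.

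Chaperones of the cytosol and mitochondria were higher in KO at 48 h in 13 of 23 genes (15 when adjusted over the list alone), with a median log2 difference of 0.28. Hsph1 stood at 0.68, Fkbp4 at 0.50, Hspd1 at 0.45, Hsp90aa1 at 0.43, Cacybp at 0.41 and Ptges3 at 0.39. Cytosolic aminoacyl-tRNA synthetases were higher in 11 of 20 (median 0.26, Tars 0.48, Lars 0.40) and purine synthesis enzymes in 5 of 10 (median 0.21, Gart 0.47, Ppat 0.34). By camera the adjusted p was 6.21e-15, 1.26e-09 and 1e-05, and with an estimated correlation adjusted p = 0.0967 for each of the 3. For the interaction the chaperones had a median of 0.40 (1.48e-25, adjusted p = 0.0955 with an estimated correlation). Part of this came from rest, where their median in KO against WT was −0.10 with 1 of 23 positive. At rest camera gave an adjusted p of 1.77e-09, and 0.315 with an estimated correlation.

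The Ly49 receptor genes stood higher in resting KO cells in 12 of 14 genes (median 0.53), with 0 called by edgeR over all genes and 5 when adjusted over the list alone. Camera gave an adjusted p of 6.66e-11, and adjusted p = 0.0614 with an estimated correlation. The first, partial list passed with an estimated correlation and the whole family did not, and Klra6 and Klra9 had been seen before the list was made. Metallothioneins and collagen hydroxylases rose on activation in WT in 7 and fell in 1 of 8 tested (median 5.14, Mt1 6.11, Plod2 5.79, Plod1 −0.99). Mt2 and P4ha2 had been seen among the largest increases before this list was made.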
